A study of Mus musculus with 5 samples.

How the data were processed

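Mouse bone marrow-derived macrophages differentiating into osteoclasts were sampled at days 0, 1, 2, 3 and 5, with 1 array per day, and each array was assigned to its day from the time given in the labels. Per the labels, total RNA was extracted with Trizol and biotinylated cDNA was made with the Affymetrix WT Pico kit from 5 ng of RNA. The deposited values are on the log2 scale and, per the submitters' processing notes, were made with RMA from the oligo package in R 3.4.0. RMA subtracts background, normalises the arrays to one distribution by quantiles and summarises the probes of a row by median polish. The summary level, the probe annotation behind it and the genome build are not given in the sources used here, and no coordinates are printed. Quantile normalisation assumes that arrays share one distribution, so a shift of all genes between days cannot be seen. Median polish gives exact ties, and 16.8% of all rows and 8.00% of measured genes held the same value at day 5 and at day 0. Background handling compresses differences near the lower end of the scale, so folds of genes near background are understated.

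The table held 41345 rows. In the platform annotation 23521 rows named 1 gene and 1814 several, and 16010 were not listed and are unnamed here. Symbols were checked through Entrez identifiers against RefSeq of assembly GRCm38.p6, where 23328 of the 23521 matched and 0 symbols changed. Rows with several genes or none were left out of gene counts. For the 1082 genes with several rows the row with the highest mean over the 5 arrays was used, giving 22180 genes. A gene counted as measured when its mean over the arrays was at or above 4.89, the median of the row means, which kept 12049 genes. Values were used as deposited.

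Each comparison is the difference of log2 values between 2 arrays, for each day against day 0 and for each step between sampled days. With 1 array per day no test of single genes was run, and a gene was counted at a difference of 1 or more in size, which is 2-fold. Fixed gene lists (39 lists with 822 entries, of which 66 had no row analysed here) and 8 gene families defined by symbol were summarised by the median of measured members. Each median was placed among 10000 random lists of the same size matched on mean level in 20 bins, a percentile that describes these arrays only. The SD of the disagreement between 2 rows of one gene, 0.59, served as a wide yardstick of measurement noise and does not cover the spread between cultures. The lists, the size and level filters, the alternatives and the rule for naming genes were chosen before the data were examined. The rule named the 12 largest increments and 12 largest decrements at day 5 against day 0 with the same sign at days 2, 3 and 5. It also named the 6 largest each way at day 1 against day 0, the 4 largest each way in each later step, and the 6 highest peaks and 6 deepest troughs at an intermediate day. In each list it named the 4 members with the largest difference at day 5 and the largest in each direction. Always named were Acp5, Ctsk, Mmp9, Nfatc1, Dcstamp, Ocstamp, Calcr, Itgb3, Atp6v0d2, Oscar, Tnfrsf11a, Car2, Csf1r, Adgre1, Irf8 and Mki67, and 1 further gene of that set was not analysed here. Predicted genes, small RNA genes, olfactory and vomeronasal receptor clusters, and immunoglobulin and T cell receptor segments were counted but not named outside the lists. For most lists only the leading ones of these are printed.

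Genes shared between comparisons with one day 0 array were set beside the number that independent lists would share and beside simulated unchanged arrays, with noise drawn from the differences between days 3 and 5, a choice made after the data were seen. The counting and the list percentiles were tested on simulated data for day 5 against day 0 over 12049 genes. Of 50 genes set 2.83-fold apart 98.0% were counted, of 50 set 1.5-fold apart 10.0%, all of those at 4-fold and 8-fold, and 17 of 11849 unchanged genes. Here too the noise was drawn from the differences between days 3 and 5, the closest arrays, with no spread between cultures. These rates were set by that choice and are not error rates of the real comparison. A raised list reached percentile 100, and 3 of 100 unchanged lists fell outside percentiles 2.5 and 97.5, the bounds of random lists used throughout. The unchanged lists were drawn at random from genes with independent noise, so this rate was nearly fixed in advance. It does not cover lists whose members vary together. Alternatives covered the scaling of the arrays, the rule for genes with several rows, the size and level filters, the days compared, the list summary and the matching of random lists. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.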

Results

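Gene expression was followed while mouse bone marrow-derived macrophages turned into osteoclasts, the multinucleated cells that resorb bone. Wild-type cells on plastic received 20 ng/ml M-CSF, the growth factor that sustains macrophages and their precursors, and 30 ng/ml RANKL, the cytokine that drives osteoclast formation. RNA was taken from the macrophages at day 0, from differentiating cells at days 1, 2 and 3, and from cells the labels call mature at day 5. Each day had 1 Affymetrix array hybridised from 5 ng of total RNA, 5 arrays in all. With no replicates there was no spread between cultures to test against, so no p-value is given and every difference compares single arrays. The number of arrays limits the precision of every value. Array medians lay between 4.88 and 4.92 on the log2 scale and upper quartiles between 7.05 and 7.17. Of 22180 genes, 12049 lay above the level filter of 4.89 and are called measured here. As a yardstick of measurement noise, the difference of day 5 from day 0 was compared between 2 rows of one gene. It disagreed with an SD of 0.59 over 500 such genes, or 0.42 for 1 row, and does not cover the spread between cultures. The differences between days 3 and 5 had an SD of 0.24 over measured genes, so this yardstick is wide for measurement noise. Values after a gene name are log2 differences, the later day minus the earlier one, and list percentiles place a list's median among 10000 random lists of equal size and similar mean level.

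The comparison of day 5 with day 0 asked how the culture called mature differs from the macrophages it came from. No array of cells kept without RANKL was part of the series, so time in culture cannot be told apart from osteoclast differentiation. Among the fixed lists, the resorption machinery, V-ATPase subunits and the tricarboxylic acid cycle stood highest over day 0 by their medians, and cell cycle, complement and granulocyte genes lowest. Of the 12049 measured genes, 817 were at least 2-fold higher at day 5 and 791 at least 2-fold lower. The higher genes reached further: 230 were at least 4-fold higher against 93 at least 4-fold lower, and 94 against 14 passed 8-fold. The level filter uses the mean over the 5 arrays. Genes low only at day 0 pass it more easily than genes high only at day 0, which can add to this difference.

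The largest increments at day 5 belonged to Car2 (6.91, 120-fold), the carbonic anhydrase that supplies protons for acid secretion, and Oscar (6.80), a collagen-binding costimulatory receptor of osteoclasts. Ctsk, the main collagen-degrading protease of the resorption pit, was 108-fold higher (6.75). Next came the hydroxysteroid dehydrogenase Akr1c18 (6.73), the sodium-proton exchanger Slc9b2 (6.66), the immunoregulatory glycoprotein Cd200 (6.52) and the actin-severing Scin (6.22). The vesicular monoamine transporter Slc18a1 (6.22), the integrin chain Itgb3 (6.12), the calcitonin receptor Calcr (6.11), the fusion gene Ocstamp (6.0) and the small GTPase Rab38 (5.87) completed the 12 largest. All of these except Ctsk had a day 0 value below the filter level, where RMA compresses differences.

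Largest among the lower genes was F13a1 (-5.01, 32.1-fold lower), which encodes a subunit of coagulation factor XIII, followed by Ctla2a (-4.90), the fatty acid desaturase Fads2 (-4.04) and fibronectin, Fn1 (-3.93). The monocyte chemoattractants Ccl2 (-3.87) and Ccl7 (-3.22) and the fractalkine receptor Cx3cr1 (-3.46) were lower as well. Fcrls, an Fc receptor-like scavenger receptor (-3.53), AI504432 (-3.50), the cyclin Ccnd2 (-3.31), the cholesterol hydroxylase Ch25h (-3.17) and the fatty acid receptor Gpr84 (-3.13) made up the rest of the 12. For Fcrls the difference lay wholly between days 0 and 1, with 5.27 on the arrays of days 1, 3 and 5 and 4.56 at day 2. Most of the difference of Ccnd2 and Ccl7 lay there too, with -0.28 and -0.40 against day 1, while F13a1 (-2.21) and Gpr84 (-2.04) were still lower. Ch25h was -1.71 when its 2 rows were averaged.

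Resorption and V-ATPase genes were higher as groups, while fusion and podosome genes were mixed. In the resorption machinery 16 of 19 measured members were at least 2-fold higher, 0 lower and 3 neither, with a median of 3.76 at percentile 100. Beside Car2, Ctsk and Slc9b2, this list held the phosphatase Acp5 (5.76) and the gelatinase Mmp9 (5.59), while Rab3d was at -0.43 (0.35 against day 1). Among V-ATPase subunits, the proton pump that acidifies the resorption pit, 10 of 17 were higher, 1 lower and 6 neither (median 1.16, percentile 100). Atp6v0d2 (5.43) led them, followed by Atp6v1d (1.96), Atp6v1c1 (1.61) and Tcirg1 (1.51), and Atp6v0a1 was the lower one (-1.10, but 0.71 above day 1). Cell fusion genes split: 6 of 13 were higher, 2 lower and 5 neither (median 0.33, percentile 98.0), with Dcstamp at 5.37 and Adam8 at -1.59. Of the genes for podosomes, the sealing zone and actin, 8 of 32 were higher, 1 lower and 23 neither (median -0.04, percentile 25.6). The kinase Src (4.31), the actin-binding Cttn (3.85) and Dock5 (2.39) were among the higher ones, and Lpxn was lower (-1.25). With day 1 in place of day 0 the resorption median was 1.93, because part of its difference was already present at day 1. The fusion median was 1.46 and the podosome one 0.57 when members were averaged, since a few large values carry both lists, and the fusion median was 0.00 without the level filter.

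Of 26 measured genes of RANK signalling and osteoclast transcription, 7 were higher, 2 lower and 17 neither (median 0.33, percentile 99.8). That median was 0.12 with the mean of a gene's rows and 0.19 with arrays centred on the reference genes. Higher were Jdp2 (3.91), an AP-1 family factor, Ppargc1b (3.26), a coactivator of mitochondrial genes, Bhlhe40 (2.92), Prdm1 (2.56) and Nfatc1 (1.76), the master regulator of osteoclast formation. Mef2c was at -1.68 in its brightest row (-0.0755 against day 1) and at -0.84 over both rows. Most of the difference of Jdp2, Bhlhe40, Prdm1 and Nfatc1 was present at day 1, against which they were at 0.24, 0.56, 0.37 and 0.26. RANK itself, Tnfrsf11a, was at 0.11, or -0.028 with arrays centred on the reference genes. In the ITAM costimulation list 2 of 15 were higher, 1 lower and 12 neither (median -0.11, percentile 14.6), with Siglec15 at 1.95 beside Oscar. The lower one was Slc8a1 (-1.04), which held 6.24 at both day 1 and day 5. Trem2, at -0.97, was neither and stood at -0.26 against day 1. Among negative regulators of osteoclast formation 0 of 17 were higher, 5 lower and 12 neither (median -0.26, percentile 1.58). These included Id1 (-2.20), the interferon regulatory factor Irf8 (-1.33) and the Notch effector Rbpj (-1.31), while Tnfaip3 was at 0.91. With day 1 as the starting point the median of this list was 0.31, Irf8 stood at 0.45 and Id1 at -0.064. These rest on the day 0 array, while Rbpj was still at -0.54. Calcium and calcineurin genes had 1 of 20 higher, 2 lower and 17 neither (median -0.04, percentile 37.4). The calcineurin regulator Rcan1 was at 2.08 and Camk1d at -1.34, but Camk1d was only at -0.16 against day 1.

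Transcripts of the tricarboxylic acid cycle and oxidative phosphorylation were higher as lists at day 5, and those of glycolysis lay within the bounds of random lists. In the tricarboxylic acid cycle 11 of 21 genes were at least 2-fold higher, 0 lower and 10 neither (median 1.09, percentile 100), among them the pyruvate dehydrogenase subunits Pdha1 (1.61) and Pdhb (1.59) and the dehydrogenases Idh3b (1.51) and Mdh2 (1.43). Of 41 nuclear-encoded oxidative phosphorylation genes 9 were higher, 0 lower and 32 neither (median 0.70, percentile 100), with Atp5d at 1.93 in its brightest row and 1.31 over its rows, and Uqcrc2 and Ndufs1 both at 1.41. With day 1 in place of day 0 the tricarboxylic acid cycle median was 0.60. In glycolysis 1 of 19 was higher, 1 lower and 17 neither (median -0.12, percentile 11). Pdk1, a kinase that restrains pyruvate dehydrogenase, was the higher one (1.24) and the hexokinase Hk3 the lower one (-1.21, but 0.21 above day 1). Lysosomal hydrolases and membrane proteins had 4 of 36 higher, 2 lower and 30 neither (median 0.09, percentile 80.3). Their median was -0.042 with arrays centred on the reference genes. The sulfatase Arsb was at 2.35 (2.97 over its rows), Slc37a2 at 1.70 and the protease Ctsc at -1.54 (-0.097 against day 1). Iron genes went both ways, with 4 of 13 higher, 4 lower and 5 neither (median 0.38, percentile 98.9). Their median was 0.15 with day 3 in place of day 5, 0.25 with arrays centred on the reference genes and 0.59 against day 1. The metalloreductase Steap4 (5.63), the transferrin receptor Tfrc (2.43) and the ferritin receptor Ncoa4 (1.78) were higher, and the heme oxygenase Hmox1 was lower (-1.52), though 0.59 above day 1.

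The sterol and lipid handling lists had lower medians at day 5. In sterol synthesis and uptake 0 of 19 were higher, 7 lower and 12 neither (median -0.65, percentile 0.01), led by squalene epoxidase, Sqle (-1.65), and the sterol carrier Stard4 (-1.39), with Insig1 at 0.30. Of 18 cholesterol efflux and lipid handling genes 2 were higher, 5 lower and 11 neither (median -0.52, percentile 0.02). The sterol transporter Abcg1 was higher (2.5), and the oxidised LDL receptor Olr1 (-1.75), the fatty acid synthase Fasn (-1.75) and Cd36 (-1.35) were lower. NRF2 and antioxidant genes had 0 of 17 higher, 2 lower and 15 neither (median -0.33, percentile 0.59), the second lower one beside Hmox1 being Gclc (-1.14), a subunit of the glutathione-synthesising ligase. With day 1 in place of day 0 the medians were 0.29 for sterol synthesis, 0.018 for lipid handling and -0.081 for NRF2 genes, so these list medians rest on the day 0 array, although Fasn was at -1.92 against day 1.

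The macrophage, Toll-like receptor, cytokine and complement lists were lower at day 5 than at day 0, by a step already present at day 1. Of 26 macrophage identity genes 2 were higher, 11 lower and 13 neither (median -0.70, percentile 0). Beside Cx3cr1, the IgG receptor Fcgr1 (-2.54) and the chemokine receptor Ccr2 (-1.84) were lower, Adgre4 was higher (2.69), the F4/80 gene Adgre1 was at -0.99 and the M-CSF receptor Csf1r at -0.14. Against day 1 these last were at 0.25 and 0.65. In the Toll-like receptor and pattern recognition list 1 of 26 was higher, 7 lower and 18 neither (median -0.73, percentile 0), with the inflammasome sensor Nlrp3 at -2.00, Tlr13 at -1.35 and the beta-glucan receptor Clec7a at 1.28. Cytokines and chemokines had 2 of 22 higher, 8 lower and 12 neither (median -0.62, percentile 0). Here Tnf (-2.26) and Cxcl14 (-2.24) were lower beside Ccl2 and Ccl7, and Lif was higher (1.94). In the complement list 3 of 11 were higher, 6 lower and 2 neither (median -1.24, percentile 0), with the anaphylatoxin receptors C5ar1 (-1.77), C5ar2 (-1.67) and C3ar1 (-1.48) lower and complement factor B, Cfb, higher (1.44). Against day 1 in place of day 0 the medians were 0.22 for macrophage identity, 0.14 for Toll-like receptors, 0.034 for cytokines and -0.090 for complement, so these medians rest on the day 0 array. Fcgr1 and Tlr13 stood at 1.07 and 0.28 above their day 1 values, but Cx3cr1 (-1.66) and Ccl2 (-1.43) lay below theirs.

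The receptor and antigen presentation lists lay within the bounds of random lists at day 5. Cytokine and growth factor receptors had 5 of 27 higher, 7 lower and 15 neither (median -0.14, percentile 7.78), with Tnfrsf9 at 4.55, the interleukin-1 receptor Il1r1 at 2.33 and the chemokine receptor Ccr1 at 2.19. Of 12 MHC class II presentation genes 3 were higher, 2 lower and 7 neither (median -0.03, percentile 40.3). Among them were the thiol reductase Ifi30 (1.62) and H2-Aa (1.11) against H2-DMb2 (-1.35, but 0.00 against day 1). In MHC class I presentation 1 of 11 was higher, the peptide transporter Tap2 (1.40), 0 lower and 10 neither (median 0.04, percentile 69.3). Interferon-stimulated genes lay slightly higher as a list (median 0.18, percentile 99.0, and 0.049 with arrays centred on the reference genes), but all 25 were neither, with Zbp1 at 0.98 and Stat2 at -0.71 (0.55 against day 1).

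Cell cycle genes were lower almost without exception. Of 38 measured genes of S phase and mitosis, 37 were at least 2-fold lower at day 5 and 0 higher, with a median of -1.82 at percentile 0. The replication licensing factor Cdc6 (-2.94), E2f8 (-2.56), the helicase Hells (-2.37) and Uhrf1 (-2.30) were lowest, the proliferation marker Mki67 was at -2.00, and E2f1 was the exception at -0.66. Cell cycle inhibitors had 2 of 15 higher, 2 lower and 11 neither (median -0.07, percentile 29.8), with Cdkn2b at 1.54 and the retinoblastoma relative Rbl1 at -2.19. Unfolded protein response genes had 0 of 18 higher, 1 lower and 17 neither (median 0.10, percentile 83.5). The lower one was the chaperone partner Sdf2l1 (-1.12, but -0.36 against day 1). Immediate early genes had 0 of 18 higher, 3 lower and 15 neither (median -0.21, percentile 3.14), led by Klf2 (-2.00, but -0.11 against day 1). The list named osteoclast-derived secreted factors had 6 of 13 higher, 1 lower and 6 neither (median 0.87, percentile 100). Among the higher ones were Bmp2 (2.02) and 2 members that are not secreted factors, the membrane ligand Efnb2 (3.73) and the lipid kinase Sphk1 (1.65). Igf1 was at -1.16, which was 0.50 above day 1. Without the level filter the median of that list was 0.018, and with the filter at the 75th percentile of rows it was 0.22.

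Markers of other cell types were checked beside these groups. Neutrophil and granulocyte markers were lower, with 6 of 13 at least 2-fold lower, 0 higher and 7 neither (median -0.98, percentile 0), among them Chil3 (-1.53), S100a9 (-1.38) and Ngp (-1.38). Their median was -0.51 with day 3 in place of day 5. Dendritic cell markers had 1 of 7 higher, Itgax (1.33, but -0.17 against day 1), and 6 neither (median 0.18, percentile 93.8). T and NK cell markers had 1 of 3 higher, Cd5 (2.71), and 2 neither (median 0.39), and stromal and osteoblast markers 1 of 3 higher, the proteoglycan Dcn (1.93, but -1.33 against day 1), and 2 neither (median 0.19). Megakaryocyte and mast cell markers had 1 of 4 lower, the platelet chemokine Ppbp (-1.84, and -0.50 against day 1), and 3 neither (median -0.41). Endothelial markers had Vwf higher (1.87), Eng (-1.30) and Cdh5 (-1.29) lower and 1 neither, with a median of -0.75 that was 0.057 without the level filter. Against day 1 Vwf was at 1.72, Eng at -0.31 and Cdh5 at 0.00. The single measured markers of B cells, Cd22 (0.19), and erythroid cells, Tal1 (-0.49, but 0.11 against day 1), and the adipocyte markers Fabp4 (0.99) and Aqp7 (0.00) were neither. Of 16 reference genes 2 were higher, Tfrc and Sdha (1.10), and 14 neither (median 0.01).

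**Figure D1:**
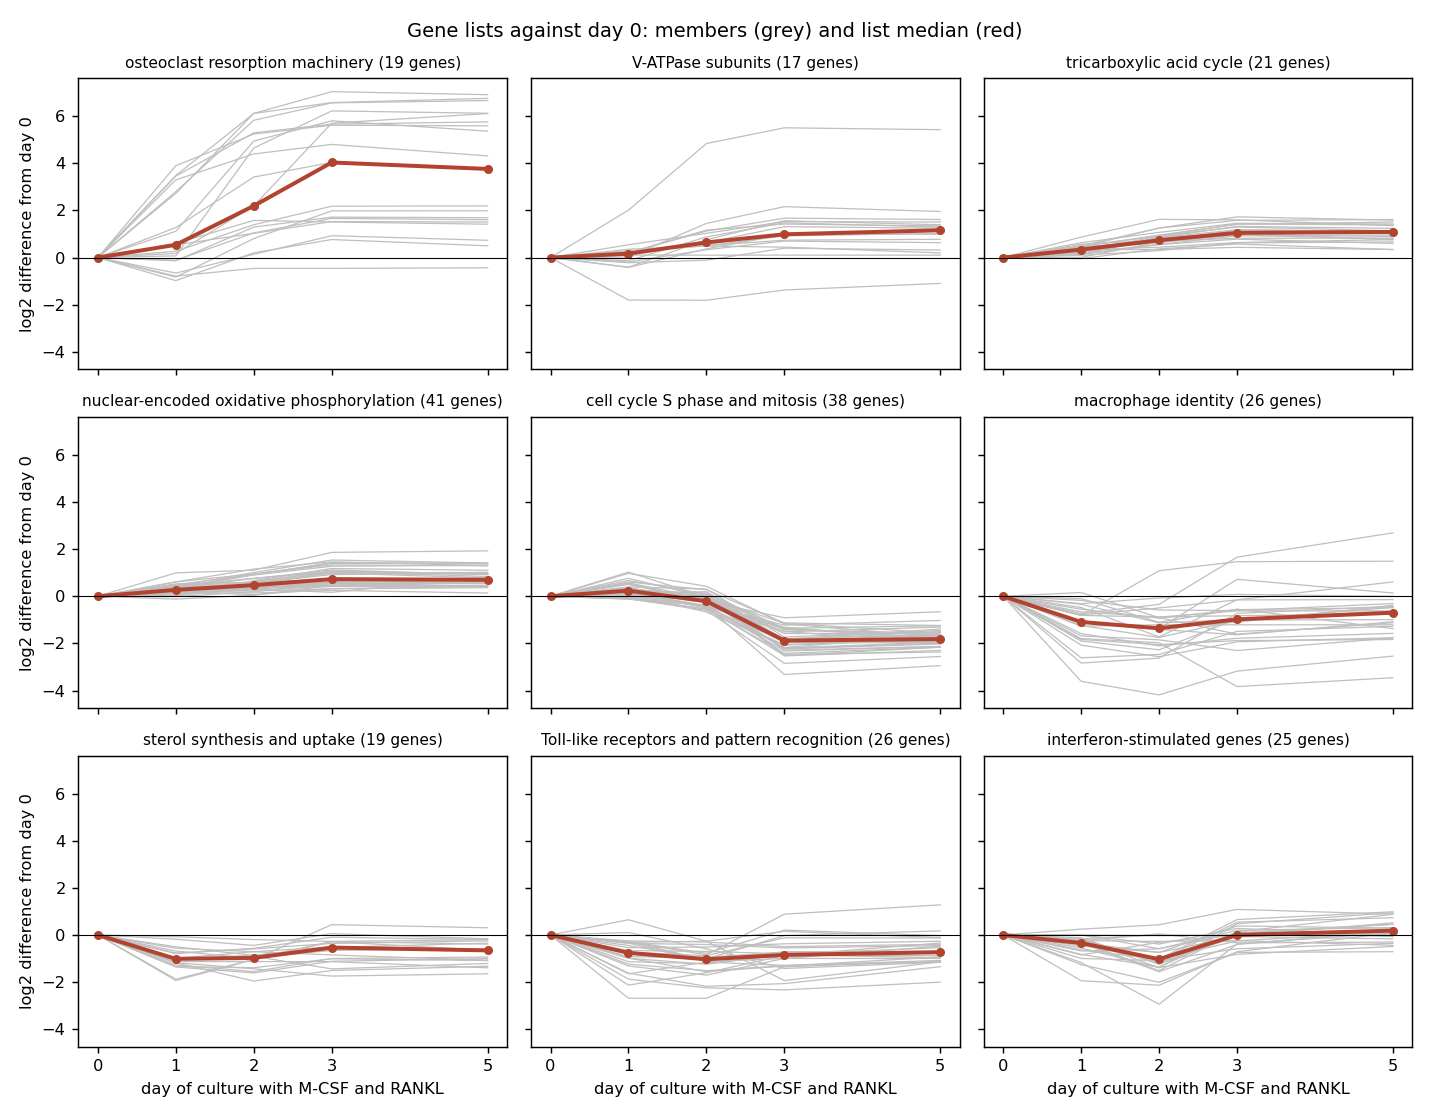
Log2 difference from day 0 (vertical axis) at days 0, 1, 2, 3 and 5 (horizontal axis) for 9 fixed gene lists, with each measured member in grey and the list median in red, 1 array per day. The resorption median reaches 4.03 at day 3 and 3.76 at day 5, the cell cycle median lies at -0.21 at day 2 and -1.88 at day 3, and the interferon median is lowest at day 2 with -1.03.

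The direction of the day 5 counts changed under 1 scaling: centring each array on the median level of the reference genes gave 676 higher and 988 lower genes. The median difference of these reference genes themselves was 0.01, so the shift came from the median of their levels and not from their typical difference. Centring on the measured genes gave 859 higher and 739 lower, and repeated quantile normalisation 818 and 791. With day 1 in place of day 0, the day 5 values of 14 named genes changed sign, 9 of them at least 2-fold apart from day 0, another 67 moved by more than 0.59 and 49 did neither. Centring on the reference genes lowered all genes against day 0 by 0.21 at day 2, 0.15 at day 3 and 0.13 at day 5, and by 0.23 between days 1 and 2.

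The step from day 0 to day 1 asked what changes within the first day of differentiation. The macrophage, sterol, Toll-like receptor and complement lists were already lower at day 1, and the resorption list was higher. The largest increment belonged to Pgf, the placental growth factor (5.96), followed by Mmp9 (3.90), the kinase anchor Akap6 (3.81), the lymphangiogenic factor Vegfc (3.73), Mycl (3.72) and Jdp2 (3.67). For Pgf and Mycl the day 0 value lay below the filter level, and for Slco2b1 the day 1 value. The largest lower values belonged to Fcgr1 (-3.61), Fcrls (-3.53) and Gas6 (-3.46), the ligand of the receptor Mertk. Next were the endosomal exchanger Slc9a9 (-3.32), the organic anion transporter Slco2b1 (-3.15, and -1.59 over its 2 rows) and Ccnd2 (-3.03). In all, 351 genes were at least 2-fold higher and 503 lower. Macrophage identity had 14 of 26 genes lower and 0 higher (median -1.09, percentile 0), and sterol synthesis had 10 of 19 lower and 0 higher (median -1.01, percentile 0). Toll-like receptors had 8 of 26 lower (median -0.76) and complement 6 of 11 (median -1.20). By contrast 8 of 19 resorption genes were already higher and 0 lower (median 0.54, percentile 100), as were 8 of 26 RANK and transcription factor genes, with 2 lower (median 0.23, percentile 97.9).

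**Figure D2:**
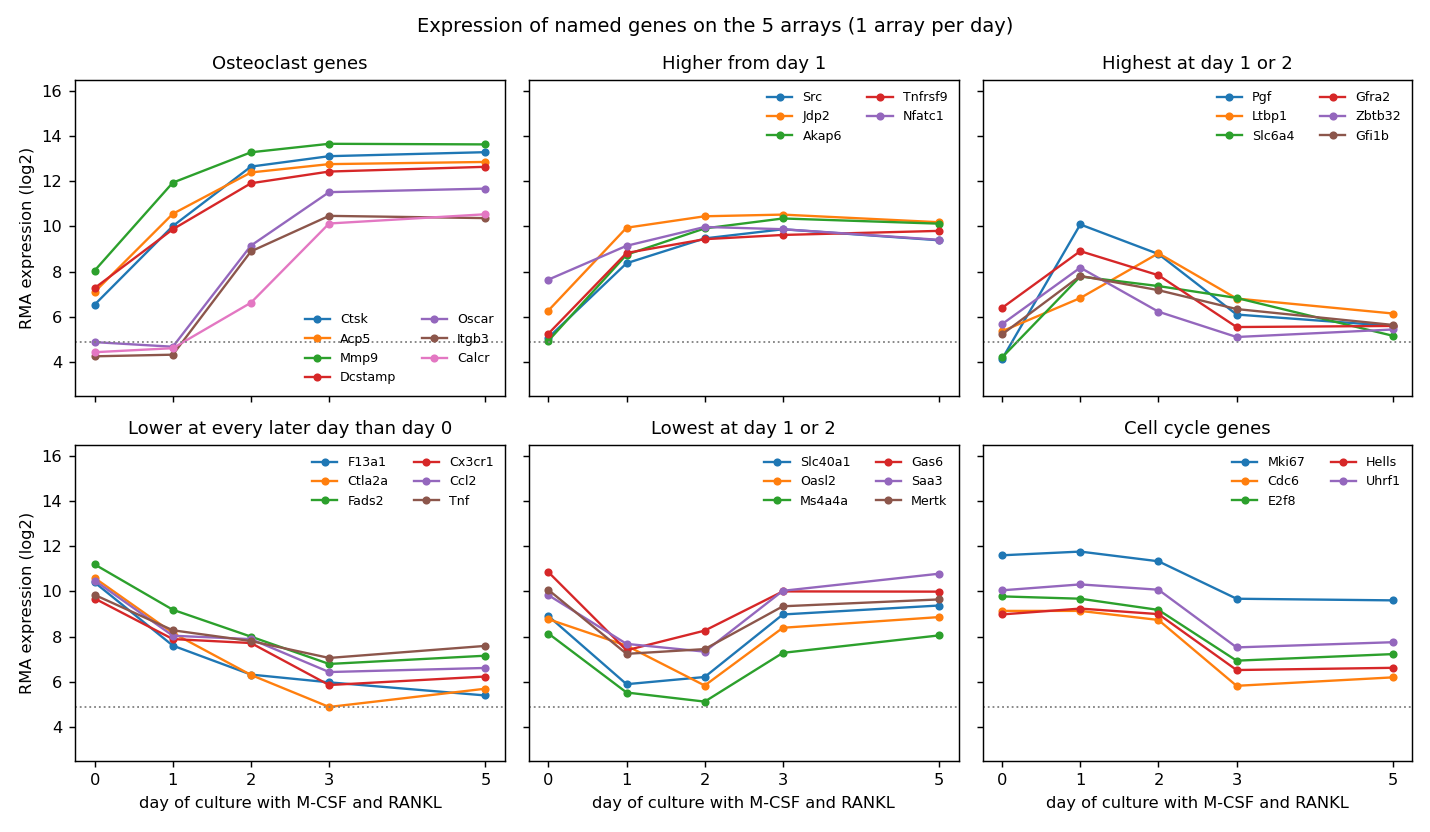
RMA expression in log2 (vertical axis) on the single array of days 0, 1, 2, 3 and 5 (horizontal axis) for named genes in 6 groups, with the level filter of 4.89 dotted. Ctsk climbs from 6.54 at day 0 to 13.29 at day 5, Pgf is highest at day 1 with 10.09, and Mki67 goes from 11.34 at day 2 to 9.68 at day 3.

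Between days 1 and 2 most resorption genes became higher. The largest increments belonged to the unconventional myosin Myo1d (5.27, 38.7-fold), Akr1c18 (5.02), Itgb3 (4.58) and Oscar (4.48), the last 3 from day 1 values below the filter. Of the 19 resorption genes 15 were at least 2-fold higher than at day 1 (median 1.43, percentile 100), and so were 4 of 17 V-ATPase subunits (median 0.49, percentile 100) and 6 of 32 podosome genes (median 0.21, percentile 99.98). With arrays centred on the reference genes these last medians were 0.26 and -0.024. Lowest were the protease inhibitor Slpi (-2.47), the transcription factor Zbtb32 (-1.95), Ctla2a (-1.86) and the interferon-stimulated gene Oasl2 (-1.77). Interferon-stimulated genes had 6 of 25 lower and 0 higher (median -0.40, percentile 0), and neutrophil markers 3 of 13 lower (median -0.85, percentile 0). In this step 297 genes were higher and 67 lower, which became 206 and 219 with arrays centred on the reference genes. Against day 0, day 2 had 624 higher and 632 lower genes, or 431 and 907 with that centring. At day 2, 14 of the 25 interferon-stimulated genes were at least 2-fold below day 0 (median -1.03, percentile 0), and 17 of 26 macrophage identity genes (median -1.36).

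Between days 2 and 3 nearly all cell cycle genes became lower. Of 38 S phase and mitosis genes 35 were at least 2-fold lower and 0 higher (median -1.67, percentile 0), and Cdc6 was lowest of all named genes (-2.92, 7.56-fold lower). The amino acid transporter Slc7a5 (-2.73), Pgf (-2.68) and the gap junction gene Gja1 (-2.67) followed. Higher were the apolipoprotein L gene Apol7c (3.95, from a day 2 value below the filter), Calcr (3.51), Steap4 (3.02) and the sialyltransferase St8sia6 (2.90). In the resorption list 3 of 19 genes were higher and 0 lower (median 0.61, percentile 100). Interferon-stimulated genes stood above day 2 again, with 12 of 25 higher and 0 lower (median 0.78, percentile 100), and 6 of 26 macrophage identity genes were higher and 1 lower (median 0.33). In total 251 genes were higher and 471 lower than at day 2. Against day 0, day 3 had 878 higher and 904 lower genes, the largest counts of any day, or 707 and 1152 with arrays centred on the reference genes.

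Days 3 and 5 were the closest pair of arrays. Only 19 genes were at least 2-fold higher at day 5 and 14 lower, 0.274% of the measured genes, against 0.75% of the genes below the filter, so these counts did not stand above noise. Highest were Polr2l (1.58), an RNA polymerase subunit, Ly6i (1.51), Trim43c (1.43) and the chemokine Cxcl14 (1.37). Lowest were the serotonin transporter Slc6a4 (-1.68), Frg2f8 (-1.44), the chitinase-like Chil3 (-1.39) and Apol7c (-1.29). Values below the filter were those of Polr2l and Trim43c at day 3 and of Frg2f8 and Chil3 at day 5. In the resorption list 0 of 19 genes differed 2-fold (median -0.03), and in the cell cycle list 0 of 38 (median 0.19). Across measured genes, which are not independent replicates, the correlation between arrays was 0.992 for days 3 and 5, against 0.903 for days 0 and 3.

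**Figure D3:**
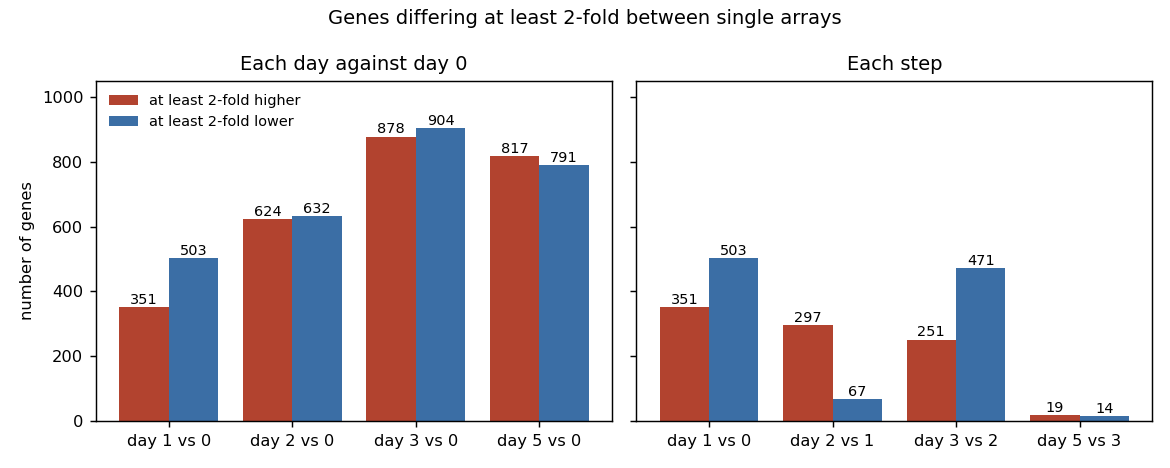
Number of genes (vertical axis, from 0) at least 2-fold higher (red) or lower (blue), out of 12049 measured genes, for each day against day 0 (left) and for each step between sampled days (right), 1 array per day. Counts peak at day 3 with 878 and 904, and the step from day 3 to day 5 has 19 and 14.

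Most of the day 5 difference was in place by day 3. Of the 817 genes higher at day 5, 178 first passed 2-fold at day 1, 304 at day 2, 242 at day 3 and 93 at day 5. Of the 791 lower genes, 261 did so at day 1, 69 at day 2, 390 at day 3 and 71 at day 5. Day 3 shared 716 higher and 703 lower genes with day 5, day 2 shared 476 and 326, and day 1 shared 178 and 261. Independent lists of these sizes would share 59.5 and 59.3, 42.3 and 41.5, and 23.8 and 33.0 genes, and simulated unchanged arrays set against the same day 0 array shared at most 3. All these comparisons use the same day 0 array, and part of the sharing can come from it. Only 15 simulated genes were higher and 9 lower at day 5, so a small share was set by the noise chosen. Neither baseline covers a day 0 array that deviates in many genes.

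Some genes peaked or dipped within the series. At an intermediate day 139 genes were at least 2-fold above both day 0 and day 5, of which 116 were highest at day 1, 17 at day 2 and 6 at day 3. Highest above both ends were Pgf (4.50 at day 1), the latent TGF-beta binding protein Ltbp1 (2.67 at day 2), Slc6a4 (2.63), the GDNF family receptor Gfra2 (2.51), Zbtb32 (2.5) and the repressor Gfi1b (2.17), the last 4 at day 1. The opposite course, at least 2-fold below both ends, was seen for 203 genes, of which 87 were lowest at day 1, 107 at day 2 and 9 at day 3. Deepest were the iron exporter Slc40a1 (3.02 below both ends at day 1), Oasl2 (2.94 at day 2), Ms4a4a (2.93 at day 2), Gas6 (2.60 at day 1), the acute phase gene Saa3 (2.5 at day 2) and the efferocytosis receptor Mertk (2.41 at day 1). Each array lay above the one before it for 336 genes (2.79%) and below it for 191 (1.59%), against 0.833% for each in random order. With a 2-fold difference between the ends these were 176 and 73 genes.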

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

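The count of list medians within 1.5 times was chosen after the result was seen. Of the counts of genes recomputed under an alternative, 57 moved and 123 stayed within 1.5 times the count reported, among them all those under centring on the measured genes, repeated quantile normalisation and both other rules for genes with several rows. Of the list medians 406 moved by less than 0.59, 19 moved further and 6 of at least that size changed sign, but this yardstick is of single genes and wide for a list. Of the medians outside the bounds of random lists, 179 kept their sign within 1.5 times under an alternative, 39 kept it beyond that and 10 changed sign or came to 0. Besides those named later these were lipid handling (0.018) and negative regulators (0.31) with day 1 in place of day 0, negative regulators (0.084) with the means of days, fusion (0.00) with no filter and at the 25th percentile, and interferon-stimulated genes (0.00) with day 3 in place of day 5. Of the values of named genes 1111 moved by less than 0.59, and 16 changed sign, of which 14 with day 1 in place of day 0. The others were Tnfrsf11a (-0.028) with arrays centred on the reference genes and Csf1r (0.25) with the means of days. Of the list percentiles 70 kept their side of those bounds and 2 moved across, both for endothelial markers. With arrays centred on the reference genes 219 genes were lower at day 2 than at day 1, by the shift of all genes. A 1.5-fold size counts more genes by construction: higher and lower were 1175 and 1179 at day 1 against day 0, 1397 and 1365 at day 2, 1662 and 1799 at day 3, and 1605 and 1686 at day 5. Between steps they were 740 and 555 (day 2 against 1), 929 and 1157 (day 3 against 2) and 182 and 171 (day 5 against 3), with 131 genes falling throughout, 690 peaks and 706 troughs. A 4-fold size gave 61 and 66, 161 and 117, 253 and 163, and 230 and 93 against day 0, then 70 and 1, 26 and 46, and 0 and 0 between steps, with 62 genes rising, 13 falling, 7 peaks and 11 troughs. A level filter at the 75th percentile tests fewer genes and gave 231 and 324, 406 and 401, 556 and 583, and 511 and 501 against day 0. Between steps it gave 181 and 40 at day 2, 127 higher at day 3, and 3 and 1 at day 5, with 115 genes rising, 36 falling and 78 peaks. That filter moved the medians of small lists, to 0.22 for secreted factors, 2.71 for T and NK cell markers, 1.33 for dendritic cell markers, 1.93 for stromal markers and -1.26 for megakaryocyte and mast cell markers, and left no endothelial member and so no value. With no filter 101 genes were lower at day 2 than at day 1, and 57 higher and 52 lower at day 5 than at day 3. The medians were then 2.98 for resorption, 0.018 for secreted factors and 0.057 for endothelial markers, a change of sign. A filter at the 25th percentile gave 37 higher and 28 lower at day 5 against day 3, and medians of 2.98, 0.19 and 0.027 for these lists, since it adds genes near background. Only genes with a single row gave 4.84 for resorption and 1.42 for fusion, and the mean of members 1.46 for fusion, 0.57 for podosomes and -0.56 for complement. The mean of days 3 and 5 against that of days 0 and 1 gave 2.91 for resorption and -0.59 for complement. With day 1 in place of day 0 resorption was at 1.93, complement at -0.090 and endothelial markers at -0.015. Sterol synthesis (0.29), macrophage identity (0.22), Toll-like receptors (0.14) and cytokines (0.034) then changed sign, as did Adgre1 (0.25), Csf1r (0.65), Rab3d (0.35), Stat2 (0.55), Tal1 (0.11) and, at least 2-fold apart from day 0, Irf8 (0.45), Atp6v0a1 (0.71), Hk3 (0.21), Hmox1 (0.59), Fcgr1 (1.07), Tlr13 (0.28), Igf1 (0.50), Itgax (-0.17) and Dcn (-1.33). Whether the day 0 array or the first day of culture gives these differences cannot be known from 1 array per day, and the cause was not tested. No paired analysis was possible because each day has 1 array and no label ties arrays to a mouse or culture. Genes near background limit what can be seen, as their differences are compressed.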

Other observations

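Among the tests below, those of a single deviating array and of expression level for the cell cycle genes, the percentile and member count at day 1 and the step from day 3 to day 5 for the interferon genes, and the step from day 2 to day 3 for the granulocyte markers were chosen after the result was seen. Gene families outside the comparisons above had time courses of their own. The 61 measured cytosolic ribosomal protein genes were higher at day 1 than at day 0 by a median of 0.29 (percentile 100 of random lists), a sign kept under all 3 scalings (0.28, 0.31 and 0.29), and lay at -0.011 at day 5, which was 0.027 with arrays centred on the measured genes, -0.15 with arrays centred on the reference genes and -0.047 after repeated quantile normalisation. Of 25 measured histone genes 12 were at least 2-fold lower at day 3 than at day 0 and 4 higher (median -0.95, percentile 0, and between -0.89 and -1.11 under the scalings). At day 5, 10 of them were lower and 4 higher (median -0.26). Unfolded protein response genes dipped at day 1, with a median of -0.54 at percentile 0, and stood at 0.00 at day 2, or -0.21 with arrays centred on the reference genes. The 36 measured lysosomal genes went from -0.38 at day 1 (percentile 0) to 0.09 at day 5, or -0.042 with that centring. Cathepsins had medians of -0.31 at day 1 and -0.45 at day 2 (percentiles 0.16 and 0.04), and Rab GTPases -0.22 at day 1 (percentile 0), signs kept under the 3 scalings.

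At day 5 the medians of other families lay within the bounds of random lists. Solute carriers had 20 of 201 measured genes at least 2-fold higher and 14 lower (percentile 40.3), Rab GTPases 2 of 48 higher and 2 lower (percentile 77.8), and sorting nexins 1 of 29 higher and 3 lower (percentile 25.4). C-type lectins had 4 of 20 higher and 2 lower (percentile 89.2), and cathepsins 2 of 13 higher and 1 lower (percentile 21.4). Genes encoded by the mitochondrial genome had 0 rows analysed here. Of the rows that named several genes, 947 passed the level filter, of which 33 were at least 2-fold higher at day 5 than at day 0 and 45 lower. Rows not listed in the annotation leaned further down, with 274 of 7065 higher and 610 lower.

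The drop of S phase and mitosis genes between days 2 and 3 was weighed against technical causes. Centring on the reference genes raised all genes by only 0.06 at day 3 against day 2, and the list median was -1.61. So small a shift could not have removed the drop, so that centring decides little. A shift common to all genes would also move random lists of similar level, and these did not reach the drop (percentile 0). The lower level at days 3 and 5 did not rest on one array. With day 2 left out, both days lay below days 0 and 1, by medians between -2.16 and -1.82. That the drop came after day 2 does rest on the single day 2 array. These tests leave biological hypotheses open. Cells may leave the cell cycle by day 3 as they fuse, or fewer cycling cells may survive or be recovered. RNA from a whole culture does not separate these, and no replicate culture was analysed here.

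Interferon-stimulated genes formed a dip, with a median at day 2 of -0.93 against the mean of days 0 and 3 (percentile 0 of random lists of similar level). A shift common to all genes would move the random lists too. With arrays centred on the reference genes the median was -1.07. That centring lowered all genes by more at day 2 than at day 3, so it could only deepen the dip and decides nothing. At day 1 the median was -0.30, so by the yardstick of 0.59 set beforehand only day 2 lay below, which would go with one deviating array. That yardstick is of single genes. Among random lists the day 1 median lay at percentile 0.025, with 24 of 25 members below the mean of days 0 and 3. Some of these were not below both days. Irf1 and Oasl1 held their day 0 value, Gbp3 lay above it, and Irf9 and Bst2 lay above day 3. The list also moved by 0.23 (percentile 100) between days 3 and 5, the closest arrays. One deviating day 2 array therefore cannot be told apart from a course over days. A candidate explanation is a passing loss of tonic interferon signalling, which was not tested.

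Neutrophil and granulocyte markers were lower at day 5, and a loss of granulocytes carried over from the marrow is one candidate explanation, since the labels name no sort or gate. Of measured members 76.9% (10 of 13) were lower by more than 0.59. With a list median of -0.98 this share could hardly have been small, so it decides nothing. Centring on the reference genes lowered all genes by 0.13 at day 5, so the median of -1.11 after it does not test scaling. A shift common to all genes would move random lists too, and the list lay at percentile 0 of these. Of the most abundant markers at days 0, 2, 3 and 5, Ngp was at 9.44, 8.32, 8.65 and 8.06, Mmp8 at 9.33, 7.84, 8.80 and 8.82 and S100a8 at 8.64, 7.44, 8.11 and 7.84, while Ly6g lay below the level filter. The list was not lower at day 1 (median 0.09) and stood 0.31 higher at day 3 than at day 2 (percentile 99.5). This 0.31 is below the yardstick of 0.59, but that yardstick is of single genes and wide for a list. A steady loss alone would not give that step, but a deviating day 2 array could. The step therefore does not decide against a steady loss. Macrophages may express some of the 13 measured members of the 16 too, so lower expression within the same cells stays open for those, as do cultures with different numbers of granulocytes.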
